A study of Mus musculus with 6 samples.

How the data were processed

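The deposited values were RPKM, reads scaled by transcript length and by mapped reads, as made by the authors per the file headers. The submitters' processing notes list TopHat2 2.0.12, Bowtie 0.12.9, HTSeq and DESeq2, and the genome builds mm8 and mm9, without saying what each did. The annotation and the tool that made the RPKM values are not given in the sources used here. The reference at hand was built on GRCm38, which differs from mm8 and mm9, so no coordinates were used and genes were matched by symbol. List genes missing from the table were looked up by older symbols, such as Emr1 for Adgre1 and Gm129 for Ciart.

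The table held 22556 genes, of which 4971 were at 0 in all libraries. Symbols merged by the authors made up 90 entries, and 25 symbols had been turned into dates, 18 of them tested. Short RNA genes numbered 726, of which 16 were tested. No mitochondrially encoded gene was listed. RPKM were used as deposited, log2 transformed after adding 0.5, and genes with a mean RPKM of at least 1 were kept, which left 11096. Fold changes on this scale understate changes of genes at a low level. Relative depth was taken from the most common ratio of RPKM to control replicate 1, over 764 to 899 low genes above 0 in both libraries.

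All 6 libraries were fitted in limma 3.58.1 with group means, moderated variances and a mean-variance trend. Residual degrees of freedom were 3 and prior degrees of freedom 4.21. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and members of a list were also adjusted over the list alone. The 3 comparisons were 7 days against control, 28 days against control and 28 against 7 days. The threshold, the comparisons, the 36 gene lists and the other settings tried were set before the data were examined. Lists with at least 3 tested members numbered 32 and were tested with camera at a correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test, were alternatives. Camera asks whether a list moved relative to the other genes and fry whether it moved at all, so a call by only 1 of them need not be a contradiction. At 28 days, however, the median of all genes was 0.01, so this difference cannot account for calls by camera alone there. Camera was also given a preset correlation, which fry was not. Replicate numbers were not taken as pairs.

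Named genes followed a rule set before the data were examined. It took the 10 highest and 10 lowest log2 changes among genes that passed and whose libraries did not overlap between groups, without predicted genes or immunoglobulin and T cell receptor segments. It added up to 4 members of each called list with the largest change, and 12 genes given in every comparison, namely Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Ctgf and Spp1. The text describes only part of the genes that the rule took, some are not reported here, and counts of named genes cover all of them. Lists share members, such as Nppa and Myl4 in the hypertrophic and atrial lists.

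In a self-test, changes were added to unchanged values made with independent normal noise at the moderated variance of each gene. These variances are drawn toward a common trend, so the shares recovered may be higher than in the data. At 7 days 89% of genes changed 2-fold and 100% of genes changed 4-fold were called, at 28 days 87% and 99%, and at 28 against 7 days 93% and 99.5%. Calls among the unchanged genes numbered 11, 12 and 16. Camera called the 1 shifted list and 0 of 30 others. Members of a list varied independently in these values, so this could not test camera on lists whose members vary together.

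Alternatives were another pseudocount, no filter, a mean RPKM of at least 5, median ratio scaling, quantile normalization, no trend, only the 2 groups compared, a replicate block, an unadjusted p with a fold threshold, and each library left out in turn. With a library left out, the lone sample of its group was assumed to vary like the other groups. Reads were not available here, so alignment, isoforms and variants were not studied. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3, were used.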

Results

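Hearts of wild-type mice were profiled by RNA sequencing during infusion of angiotensin II (Ang II), a peptide hormone that narrows blood vessels and raises blood pressure. The hormone was delivered under the skin by osmotic minipump at 1000 ng per kg per min, and hearts were taken after 7 or 28 days. The control group is listed at 0 days of infusion. Each of the 3 groups held 2 libraries, 6 in all, and each gene had 1 RPKM value per library. The labels do not say what the control mice received, at what time of day hearts were taken, or that each library came from a separate mouse. The p-values therefore measure the spread between these samples, which may be technical.

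Depth was estimated from the most common ratio of low RPKM values between libraries. Relative to control replicate 1, depth was 1.05 in control replicate 2, 1.17 and 1.14 in the 7 day libraries and 0.985 and 0.89 in the 28 day libraries. Between 15636 and 16036 genes lay above 0 RPKM in a library. Replicates differed with an SD of the log2 ratio of 0.313 in the controls, 0.434 at 7 days and 0.397 at 28 days. Without short RNA genes these were 0.257, 0.277 and 0.343. A mean RPKM of at least 1 was reached by 11096 genes, which were tested.

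The first comparison asked which genes differed from the controls after 7 days of infusion. Matrix genes had many of the largest increases. Postn, which encodes the matrix protein periostin, rose from 13.7 ± 0.628 to 148 ± 0.361 RPKM (mean ± SD, n = 2; log2 fold change 3.38, SE 0.10; limma adjusted p = 2.66e-05). Timp1, an inhibitor of matrix metalloproteinases, rose by 3.58 on the log2 scale to 41.4 ± 5.62 RPKM (limma adjusted p = 0.000266). Col1a1 and Col3a1, the main chains of type I and type III fibrillar collagen, rose by 2.53 and 2.60 on the log2 scale. Col3a1 went from 35.9 ± 3.08 to 220.1 ± 21.7 RPKM. The secreted matrix genes Thbs4, Cthrc1 and Cilp rose by 3.96, 3.89 and 3.51, and Spp1, which encodes osteopontin, by 3.22. Of 38 tested genes of collagens and matrix structure, 36 rose and 2 did not pass, and 36 rose when adjusted over the list alone. Their median log2 change of 1.81 lay 1.67 above the median of all tested genes, which was 0.14. The camera test gave adjusted p = 2.24e-26, and adjusted p = 0.257 with an estimated correlation.

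Other groups of fibroblast and matrix genes also rose at 7 days. Of 30 tested genes of matrix crosslinking and turnover, 16 rose and 2 fell, and 23 rose and 2 fell when adjusted over the list alone. Lox, which crosslinks collagen, rose by 2.27 and the membrane-bound protease Mmp14 by 2.38 on the log2 scale. The list's median lay 0.70 above that of all genes (camera adjusted p = 1.18e-07; adjusted p = 0.326 with an estimated correlation). Of 21 tested genes of TGF-beta signalling and myofibroblasts, 12 rose, and 14 adjusted over the list alone. Ltbp2, a binding protein of latent TGF-beta, rose by 2.77 and the transcription factor Meox1 by 2.37. That list's median lay 0.66 above all genes (camera adjusted p = 0.000116; adjusted p = 0.325 with an estimated correlation). Of 15 tested fibroblast markers, 9 rose, and 10 adjusted over the list alone. They included Col1a2, at 2.09, and Vim, which encodes vimentin, at 1.45. The fibroblast list, which shares 5 genes with the collagens, lay 0.85 above all genes (camera adjusted p = 3.69e-05; adjusted p = 0.257 with an estimated correlation). Ctgf, a growth factor of connective tissue, went from 32.2 ± 15.0 to 144 ± 105 RPKM and did not pass (limma adjusted p = 0.0823). It passed without either 28 day library, but these are not in this comparison. Its log2 change stayed at 2.00, and only the shared spread changed.

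Cardiomyocyte stress genes rose at 7 days. Nppb, which encodes B-type natriuretic peptide, rose from 83.8 ± 21.7 to 577 ± 189 RPKM (n = 2; log2 fold change 2.76, SE 0.28; limma adjusted p = 0.00193). Acta1, the skeletal form of alpha-actin, rose from 147 ± 32.5 to 873 ± 3.7 RPKM, a log2 change of 2.58. Rcan1, a regulator of calcineurin, rose by 2.53. Of 13 tested hypertrophic and fetal cardiomyocyte genes, 7 rose and 6 did not pass, and 10 rose when adjusted over the list alone. The median lay 1.10 above all genes (camera adjusted p = 2.11e-05; adjusted p = 0.32 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, was listed at 215 and 1605 RPKM in the control libraries and had a mean of 2008 ± 108 at 7 days. Its log2 change of 1.77 did not pass (limma adjusted p = 0.179), and was 3.22 without control replicate 2 (limma adjusted p = 0.00824) and 0.32 without control replicate 1 (limma adjusted p = 0.673). The atrial markers Myl7, Myl4 and Sln also differed between the control libraries, at 52.5 against 646 RPKM for Myl7. Myh7, the slow myosin heavy chain, had a log2 change of 0.67 (limma adjusted p = 0.167). It passed without either 28 day replicate at the same log2 change, so only the shared spread differed. Myh6, the main adult myosin heavy chain, was 0.09 and below 0 with either rescaling of the libraries. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was -0.05. Of 19 adult sarcomere genes, 4 rose and 1, Tcap, fell. That list was not called (camera adjusted p = 0.495), and its median of 0.02 and mean of 0.05 were above 0 while camera pointed below.

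**Figure D1:**
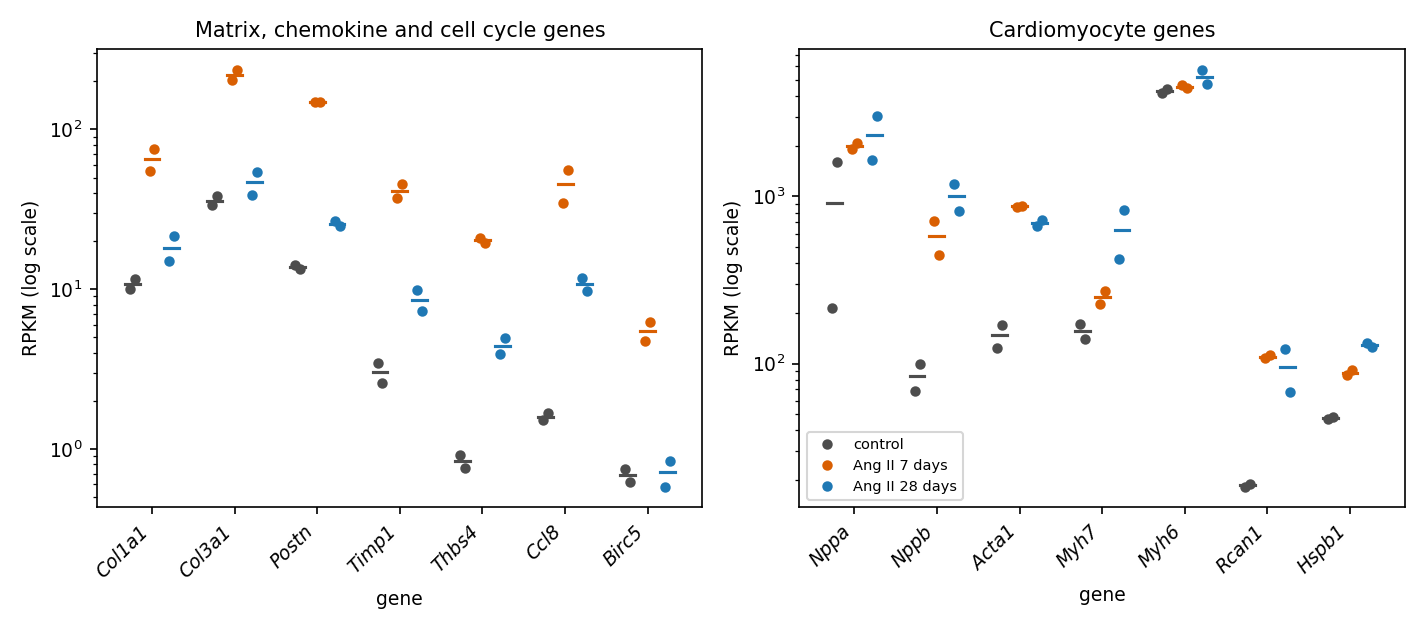
RPKM on a log axis of selected genes in the control, 7 day and 28 day groups, with matrix, immune and cell cycle genes on the left and cardiomyocyte genes on the right. Dots are libraries and bars are group means; Postn went from 13.7 to 148 and then 25.7 RPKM, and Nppb from 83.8 to 577 and then 1002 RPKM.

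Heat shock genes lay high and genes of energy metabolism low as lists at 7 days, the latter lower in 7 day replicate 2 than in replicate 1. Of 13 heat shock genes, 5 rose, and 8 adjusted over the list alone. Hspb6, Hspb7 and Hspb1 rose by 0.96, 0.94 and 0.90 on the log2 scale (list median 0.47 above all genes; camera adjusted p = 0.0129; adjusted p = 0.535 with an estimated correlation). Of 29 genes of fatty acid oxidation, 1 fell, and 0 adjusted over the list alone. It was Ppargc1a, a coactivator of mitochondrial gene expression, which fell by 0.57 (limma adjusted p = 0.0413). The list's median lay at -0.37 relative to all genes (camera adjusted p = 1.18e-07; adjusted p = 0.441 with an estimated correlation). Against the control mean it was -0.12 in 7 day replicate 1 and -0.32 in replicate 2. Of 65 genes of oxidative phosphorylation, 1 fell, and 0 adjusted over the list alone. It was Ndufs1, a subunit of complex I, which fell by 0.45 (limma adjusted p = 0.049). The calls of Ppargc1a and Ndufs1 were each lost without either control or either 7 day library, with adjusted p up to 0.191 and 0.234. Without 7 day replicate 1, Cox7a1, Cox7c, Ndufb2, Hadhb and Hadh passed lower (limma adjusted p from 0.0172 for Cox7a1 to 0.0498 for Hadh). Hadh and Ucp3 also passed without either 28 day library. Their log2 changes stayed at -0.43 and -0.81, so only the shared spread differed. The oxidative phosphorylation list lay at -0.27 relative to all genes (camera adjusted p = 8.3e-09; adjusted p = 0.535 with an estimated correlation). Against the control mean its median was -0.02 in 7 day replicate 1 and -0.26 in replicate 2, so its fall came mainly from replicate 2. Of 20 genes of the tricarboxylic acid cycle 0 passed in limma, over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Their median lay at -0.33 relative to all genes (camera adjusted p = 2.11e-05; adjusted p = 0.441 with an estimated correlation). Set against the control mean, it was -0.08 in 7 day replicate 1 and -0.29 in replicate 2.

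Immune genes rose at 7 days. Ccl8, a chemokine that attracts monocytes, rose from 1.59 ± 0.113 to 45.3 ± 15.1 RPKM (n = 2; log2 fold change 4.42, SE 0.22; limma adjusted p = 0.000241). Of 25 tested monocyte and macrophage markers, 21 rose and 4 did not pass, and 22 rose when adjusted over the list alone. Lgals3, Trem2, Ccr2 and Cx3cr1 rose by between 1.51 and 1.66 on the log2 scale. The list's median lay 0.79 above all genes (camera adjusted p = 7.71e-09; adjusted p = 0.326 with an estimated correlation). Of 20 tested chemokine, cytokine and adhesion genes, from a list of 34, 11 rose, and 12 adjusted over the list alone. Ccl2, a chemokine that draws in monocytes, rose by 1.77. That list lay 0.56 above all genes (camera adjusted p = 0.000474; adjusted p = 0.387 with an estimated correlation). Of 13 complement and acute phase genes, 10 rose, and 11 adjusted over the list alone. The protease inhibitor Serpina3n rose from 3.6 ± 0.158 to 61.1 ± 23.7 RPKM, a log2 change of 3.86. The acute phase list lay 1.24 above all genes (camera adjusted p = 2.03e-05; adjusted p = 0.441 with an estimated correlation). Against the control mean its median was 0.89 in 7 day replicate 1 and 1.86 in replicate 2. Of 23 interferon response genes 0 passed in limma, over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. Their median was 0.06, and lay below 0 with either rescaling (camera adjusted p = 0.162, pointing below). The interferon list was called without control replicate 2, at -0.34 (camera adjusted p = 1.8e-05), and without 7 day replicate 2, at -0.14 (camera adjusted p = 0.00294). The 3 tested neutrophil markers of 12 had a median of 1.66, or 0.17 for the list without a filter on low values, and 0 passed, against 2 higher at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p = 0.23).

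Cell cycle genes rose and clock genes moved in both directions at 7 days. Of 17 tested cell cycle genes, 12 rose and 5 did not pass, and 13 rose when adjusted over the list alone. The list held 34 genes, and the others did not reach the mean RPKM for testing. Genes raised in 1 group reach that mean more easily. Birc5, Cdc20, Ube2c and Ccna2, which act in mitosis or cell cycle progression, rose by 2.32, 2.38, 2.50 and 2.15 on the log2 scale. The list lay 1.15 above all genes (camera adjusted p = 7.86e-07; adjusted p = 0.325 with an estimated correlation). Of 17 circadian clock genes, 4 rose and 8 fell, and 4 rose and 10 fell adjusted over the list alone. Arntl, which encodes the clock activator BMAL1, rose from 0.526 ± 0.473 to 9.51 ± 0.04 RPKM (log2 3.37). The clock output gene Dbp fell from 51.9 ± 4.01 to 2.36 ± 0.8 RPKM (log2 fold change -4.22, SE 0.20; limma adjusted p = 0.000233). Per2, a repressor of the clock, fell from 6.73 ± 1.01 to 0.421 ± 0.258 RPKM. Per3 fell by 2.99, and Tef, Hlf and Nr1d2 by 2.13, 2.04 and 1.93. The clock list lay at -0.90 relative to all genes (camera adjusted p = 1.6e-08; adjusted p = 0.24 with an estimated correlation). Of 16 immediate early genes, 4 rose, and 6 adjusted over the list alone. Atf3, a stress-induced transcription factor, rose by 1.69. That list lay 0.49 above all genes (camera adjusted p = 0.0149; adjusted p = 0.535 with an estimated correlation). Its call was lost without control replicate 2 (camera adjusted p = 0.0822) and without 7 day replicate 1 (camera adjusted p = 0.203). A mean RPKM of at least 5 also ended it (camera adjusted p = 0.12). Inmt, Adh1 and Nmb fell by 2.72, 2.06 and 1.69, and Zbtb16 by 1.92. The call of Zbtb16 was lost without either control library (limma adjusted p = 0.0904 and 0.0803). Sprr1a was listed at 0 in both controls and at 8.31 ± 3.39 RPKM at 7 days.

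**Figure D2:**
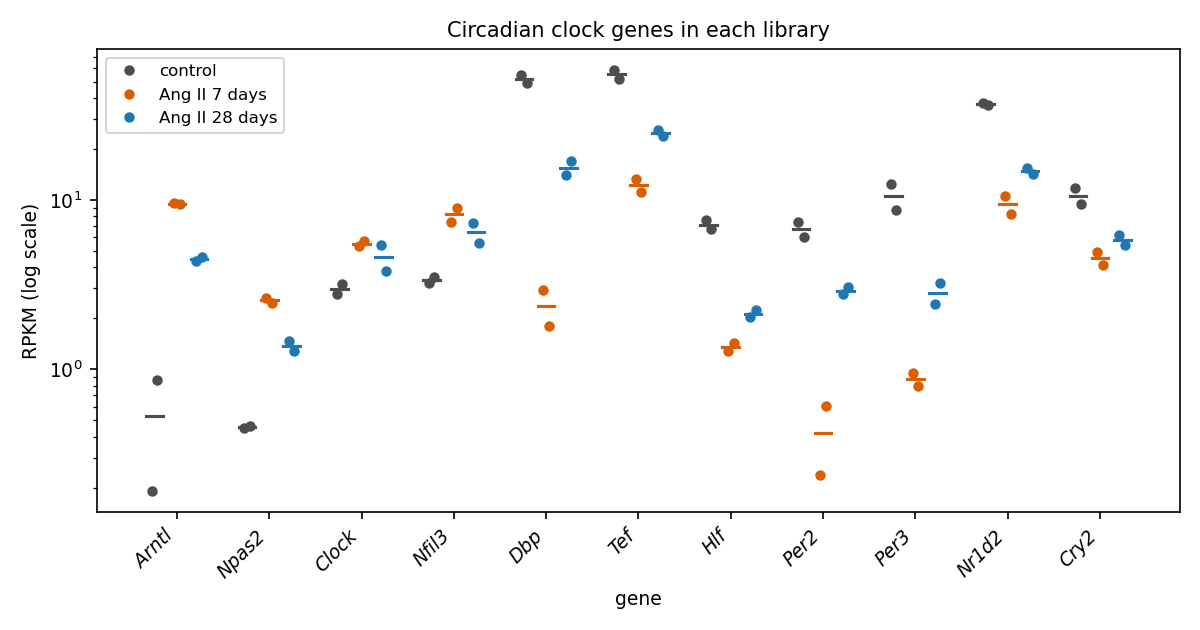
RPKM on a log axis of circadian clock genes in the control, 7 day and 28 day groups, with dots for libraries and bars for group means. Arntl lay above and Dbp below the controls at both times, with log2 fold changes of 3.37 and -4.22 at 7 days and 2.36 and -1.72 at 28 days.

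At 7 days 1461 genes were higher and 252 lower than in the controls by limma (adjusted p under 0.05), of which 370 and 49 changed over 2-fold. The higher genes made up 85.3% of the calls as deposited, 63.1% after median ratio scaling and 57.1% after quantile normalization. The counts were 340 and 52 without control replicate 1, 467 and 60 without control replicate 2, 691 and 138 without 7 day replicate 1, and 351 and 63 without 7 day replicate 2. Of 59 named genes that passed, 44 kept their call without any single library. The lists of calcium handling and ion channels, endothelial, smooth muscle, glycolysis, renin-angiotensin, redox, endoplasmic reticulum stress, red blood cell, adipocyte, mesothelial, atrial, skeletal muscle, sex-specific and ribosomal protein genes were not called at 7 days. The camera adjusted p of these lists lay between 0.112 and 0.861. The redox list was called higher without a filter on low values (camera adjusted p = 0.0214), and the renin-angiotensin list lower with a mean RPKM of at least 5 (camera adjusted p = 0.0304). Fry, a rotation test, sets a list against no change, where camera sets it against the other genes. It called 13 lists at 7 days, among them glycolysis and redox, both higher (adjusted p = 0.00475 and 0.015). Of the lists that camera called, it did not call fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle or the immediate early genes (adjusted p = 0.251, 0.488, 0.251 and 0.0752). The calcium list had a median of 0.01 with mean and camera below 0, and the renin-angiotensin list had a median of -0.04 with a mean of 0.04 and camera below. Without control replicate 1 the red blood cell list was called higher, at 1.31, and the atrial list lower, at -3.15. Without 7 day replicate 1 the endothelial list was called higher, at 0.40, and the skeletal muscle list lower, at -0.87. Without 7 day replicate 2 the ribosomal list was called higher, at 0.28 (camera adjusted p = 0.00579).

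**Figure D3:**
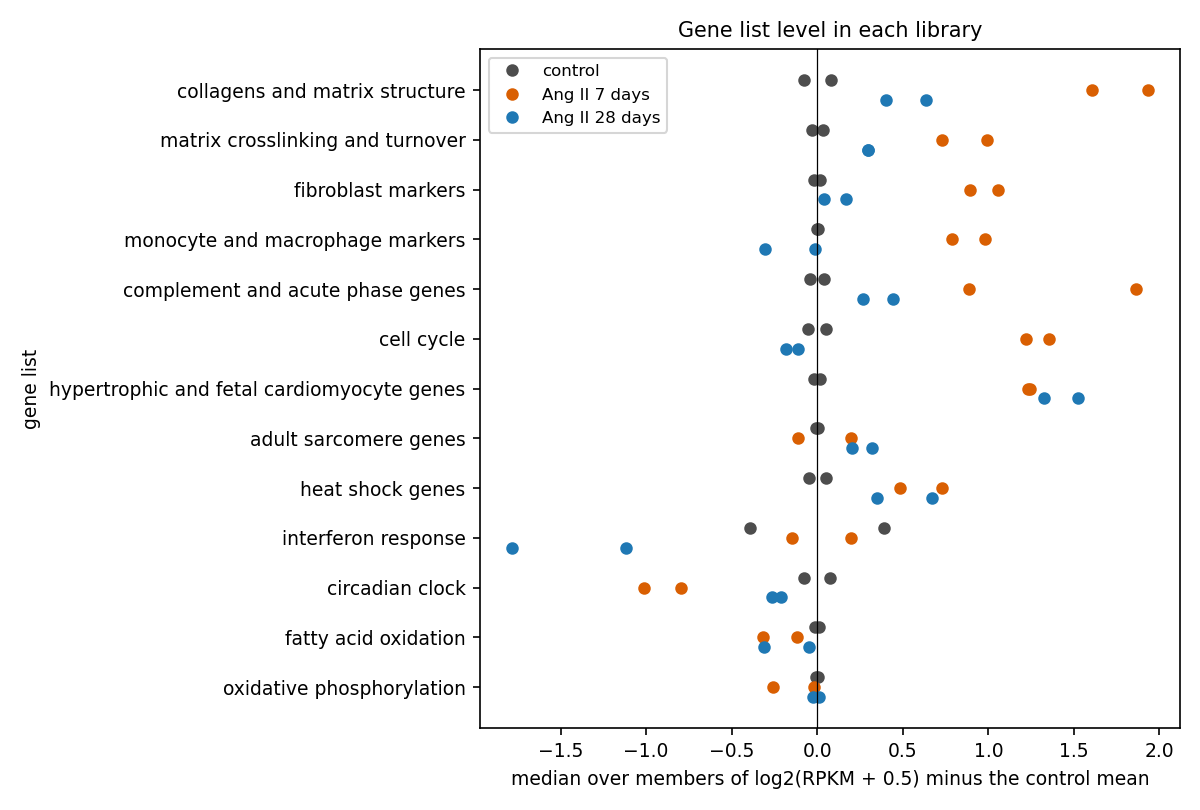
Median log2 level of 13 gene lists in each library relative to the control mean, with dots for the libraries of the control, 7 day and 28 day groups. The collagen list lay at 1.60 and 1.93 in the 7 day libraries and at 0.40 and 0.64 in the 28 day libraries, and the interferon list at -1.78 and -1.12 in the 28 day libraries.

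The second comparison asked which genes differed from the controls after 28 days. Nppb was among the highest, at 1002 ± 263 RPKM (n = 2; log2 fold change 3.57, SE 0.28; limma adjusted p = 0.00305). Acta1 rose to 693 ± 38.1 RPKM, a log2 change of 2.24, and the muscle ankyrin repeat gene Ankrd23 rose by 2.40. Tnfrsf12a, the receptor for the cytokine TWEAK, rose from 22.2 ± 2.54 to 153 ± 46.9 RPKM, a log2 change of 2.73. Syt12 rose by 2.50. Rcan1 and the cell cycle inhibitor Cdkn1a rose by 2.26 and 2.62, but lost their calls without control replicate 1 (limma adjusted p = 0.0615 and 0.104). Myh7 rose from 157 ± 22.9 to 628 ± 291 RPKM, a log2 change of 1.92 (limma adjusted p = 0.0208). Its call was lost without control replicate 1, control replicate 2 or 7 day replicate 1 (adjusted p = 0.104, 0.101 and 0.0508). Of 13 hypertrophic and fetal genes, 8 rose, and 11 adjusted over the list alone. The median lay 1.48 above all genes, whose median at 28 days was 0.01 (camera adjusted p = 4.8e-11; adjusted p = 0.358 with an estimated correlation). Nppa had a log2 change of 1.93 that did not pass (limma adjusted p = 0.217). Its change was 3.38 without control replicate 2 and 0.48 without control replicate 1. Without control replicate 2 the atrial list, which holds Nppa, had a median of 2.23. Myl7 was at 52.5 RPKM in control replicate 1 and at 341 and 182 RPKM at 28 days. The Nppa change was therefore not separated from a varying share of atrial tissue. Myh6 was 0.28, and below 0 after quantile normalization, and Atp2a2 was -0.21.

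Sarcomere, heat shock and ribosomal protein genes lay above the controls as lists at 28 days. Of 19 adult sarcomere genes, 6 rose, and 7 adjusted over the list alone. Des, which encodes desmin, and Actn2, the alpha-actinin of the Z disc, rose by 0.90 and 0.75 on the log2 scale. Both calls were lost without control replicate 1 (limma adjusted p = 0.119 and 0.179) and without control replicate 2 (0.07 and 0.0886). The sarcomere list lay 0.26 above all genes (camera adjusted p = 2.59e-05; adjusted p = 0.358 with an estimated correlation), and was not called after quantile normalization (camera adjusted p = 0.135). Of 13 heat shock genes, 4 rose, and 9 adjusted over the list alone. Hspb1 and Hspb7 rose by 1.44 and 1.39, and the list lay 0.47 above all genes (camera adjusted p = 1.09e-06; adjusted p = 0.358 with an estimated correlation). Of 77 ribosomal protein genes, 4 rose, and 18 adjusted over the list alone. The highest was Rps15, at 0.63, whose call was lost without control replicate 1 (limma adjusted p = 0.271), control replicate 2 (0.17), either 7 day library (0.0568 and 0.0563) or 28 day replicate 2 (0.0711). The ribosomal list lay 0.21 above all genes (camera adjusted p = 2.01e-06; adjusted p = 0.543 with an estimated correlation).

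Ucp3, a mitochondrial uncoupling protein, fell from 42.9 ± 3.23 to 10.3 ± 3.6 RPKM at 28 days (n = 2; log2 fold change -2.05, SE 0.25; limma adjusted p = 0.00991). Its call was lost without control replicate 1 (adjusted p = 0.0783). It was the 1 gene of 29 in fatty acid oxidation that fell, over all genes and adjusted over the list alone. That list lay at -0.23 relative to all genes (camera adjusted p = 0.00927; adjusted p = 0.777 with an estimated correlation) and was not called without 28 day replicate 2 (camera adjusted p = 0.802). Pdk4 passed lower without 28 day replicate 1 (limma adjusted p = 0.0139). Of 21 glycolysis genes, Pgam1 and Hk1 rose, by 0.79 and 0.63, and 7 rose and 1 fell adjusted over the list alone. Both genes lost their calls without control replicate 1 (limma adjusted p = 0.178 and 0.323), control replicate 2 (0.125 and 0.168) or 28 day replicate 2 (0.0556 and 0.123), and Hk1 also without either 7 day library (0.0674 and 0.0671). The glycolysis list lay 0.14 above all genes (camera adjusted p = 0.0475; adjusted p = 0.358 with an estimated correlation). It was not called without control replicate 1 (camera adjusted p = 0.057), control replicate 2 (0.0985) or 28 day replicate 1 (0.153), nor after quantile normalization (0.413) or without a filter on low values (0.0519). The replicate block also ended that call (camera adjusted p = 0.08). The oxidative phosphorylation and tricarboxylic acid cycle lists were not called (camera adjusted p = 0.859 and 0.409), but were after quantile normalization (camera adjusted p = 1.2e-05 and 0.00135, both lower).

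Matrix genes lay closer to the controls at 28 days than at 7 days. Of 38 genes of collagens and matrix structure, 9 rose and 29 did not pass, and 19 rose when adjusted over the list alone. Thbs4 and Cilp rose by 1.87 and 1.88 on the log2 scale (limma adjusted p = 0.00305 and 0.00264). Col1a1 and Col3a1 had changes of 0.71 and 0.36 and did not pass (limma adjusted p = 0.105 and 0.267). Postn rose by 0.88 and Timp1 by 1.37, and both calls were lost without control replicate 1 (adjusted p = 0.074 and 0.0615) or control replicate 2 (adjusted p = 0.0631 and 0.0678). Spp1 had a change of 0.52 (limma adjusted p = 0.212). Ctgf had a change of 2.68 (limma adjusted p = 0.0675) and passed without 28 day replicate 2 (adjusted p = 0.049). The collagen list lay 0.51 above all genes (camera adjusted p = 3.18e-11; adjusted p = 0.358 with an estimated correlation). Of 30 genes of crosslinking and turnover, 5 rose, and 10 rose and 2 fell adjusted over the list alone. Mmp14 rose by 1.19, and its call was lost without control replicate 1 (limma adjusted p = 0.0599). That list lay 0.29 above all genes (camera adjusted p = 0.000297; adjusted p = 0.486 with an estimated correlation). Of 21 TGF-beta and myofibroblast genes, 4 rose, and 6 adjusted over the list alone. Tgfb2, a TGF-beta ligand, rose by 1.36, and lost its call without control replicate 1 (limma adjusted p = 0.0725) or control replicate 2 (0.064). That list lay 0.34 above all genes (camera adjusted p = 0.000297; adjusted p = 0.358 with an estimated correlation). The fibroblast markers had 2 higher genes of 15, and 2 adjusted over the list alone, and were not called (camera adjusted p = 0.22), but were without 28 day replicate 2 (camera adjusted p = 0.0414) and by fry (adjusted p = 0.04).

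The 3 tested neutrophil markers rose, also adjusted over the list alone. S100a8 and S100a9, the subunits of calprotectin, went from 0.644 ± 0.447 to 33.6 ± 25.7 RPKM and from 0.809 ± 1.14 to 39.8 ± 34.8 RPKM. The 28 day libraries were at 15.5 and 51.8 RPKM for S100a8. The log2 changes were 4.72 and 4.95 (limma adjusted p = 0.013 and 0.0236), and Retnlg rose by 3.02. The call of Retnlg was lost without control replicate 1 (limma adjusted p = 0.178), control replicate 2 (0.0806) or either 7 day library (0.0521 and 0.052). The call of S100a8 was lost without control replicate 1 (adjusted p = 0.0934). That of S100a9 was lost without control replicate 2 (0.0731), 7 day replicate 1 (0.059) or 7 day replicate 2 (0.0577). The neutrophil list lay 4.71 above all genes (camera adjusted p = 0.000348; adjusted p = 0.358 with an estimated correlation). Only 3 of its 12 genes reached the mean RPKM for testing. Without that filter its median was 0.71, and camera called it too. Ccl8 rose by 2.43 (limma adjusted p = 0.00454). Of 13 complement and acute phase genes, Serpina3n and C4b rose, by 1.79 and 1.07, and 5 adjusted over the list alone. Both calls were lost without control replicate 1 (limma adjusted p = 0.102 and 0.193) or control replicate 2 (0.0703 and 0.127), and C4b also without either 28 day library (0.0676 and 0.052). That list lay 0.32 above all genes (camera adjusted p = 0.00118; adjusted p = 0.635 with an estimated correlation), and was not called without 28 day replicate 1 (camera adjusted p = 0.171). Saa3 passed higher without either 7 day library, though these are not in this comparison, and Hp without 28 day replicate 2. The monocyte and macrophage list, with 2 lower of 25 and 2 adjusted over the list alone, had a median of -0.14 and was not called (camera adjusted p = 0.0829). It was called lower without 28 day replicate 1, at -0.31 (camera adjusted p = 0.0006), and with a mean RPKM of at least 5, at -0.20 (camera adjusted p = 0.0221). Of 17 cell cycle genes 0 passed in limma, over all genes or adjusted over the list alone, and 1 was higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.257).

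Of 23 interferon response genes, 8 fell at 28 days and 15 did not pass, and all 23 fell when adjusted over the list alone. Iigp1 and Irgm2, interferon-induced GTPases, fell from 82.5 ± 17.0 to 15.1 ± 7.65 RPKM and from 26.8 ± 6.14 to 6.78 ± 3.78 RPKM. The log2 change of Iigp1 was -2.49 (n = 2; limma adjusted p = 0.0115), and that of Irgm2 passed too (limma adjusted p = 0.0249). The guanylate-binding proteins Gbp3, Gbp4 and Gbp5 fell by 1.85, 1.79 and 1.84, and Ifit1 by 2.20 (limma adjusted p = 0.0486). The calls of Iigp1, Irgm2, Gbp3, Gbp4, Gbp5 and Ifit1 were lost without control replicate 1 (adjusted p from 0.0615 for Iigp1 to 0.26 for Ifit1). They were also lost without control replicate 2 (adjusted p from 0.057 for Ifit1 to 0.124 for Irgm2). Without 7 day replicate 1 the calls of Irgm2, Gbp3, Gbp4, Gbp5 and Ifit1 were lost (adjusted p from 0.062 for Gbp4 to 0.0935 for Ifit1). Those genes were also lost without 7 day replicate 2 (adjusted p from 0.0607 for Gbp4 to 0.0921 for Ifit1). Without 28 day replicate 1, Gbp3, Gbp5 and Ifit1 were lost (adjusted p = 0.0619, 0.0769 and 0.0965). The interferon list lay at -1.40 relative to all genes (camera adjusted p = 1.34e-15; adjusted p = 0.426 with an estimated correlation), and was called lower without any single library.

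**Figure D4:**
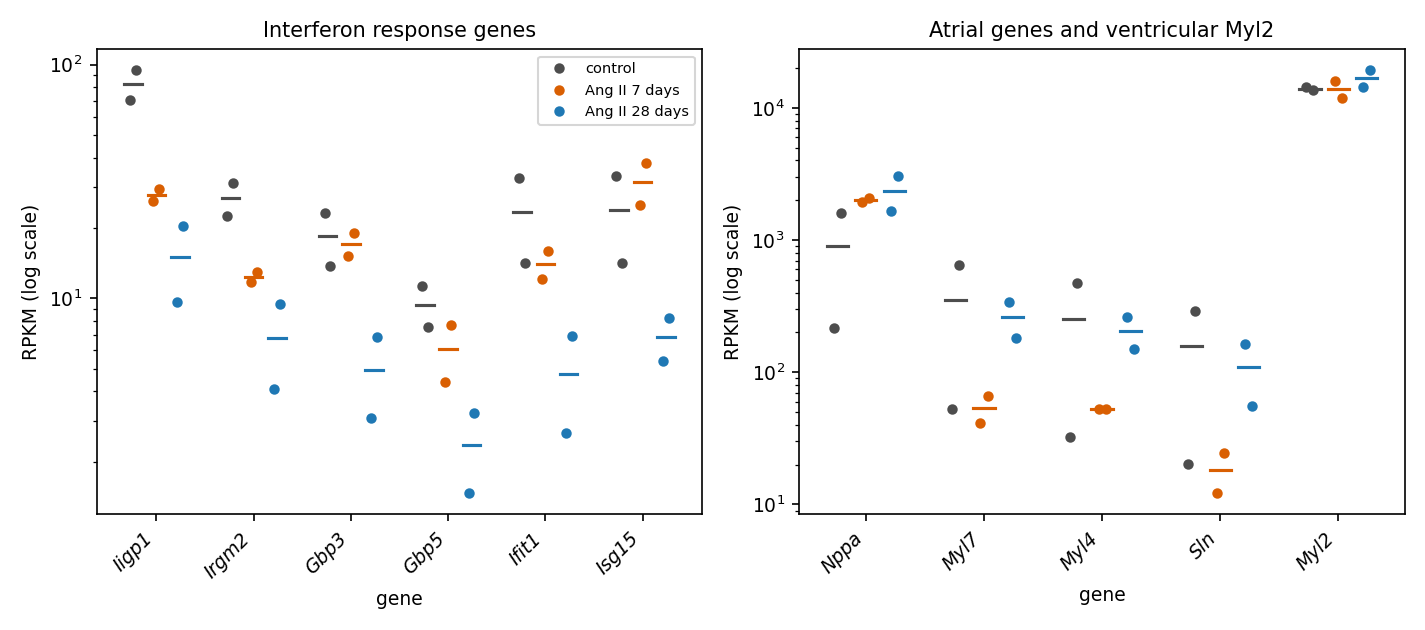
RPKM on a log axis of interferon response genes and of atrial and ventricular genes in each library of the control, 7 day and 28 day groups, with dots for libraries and bars for group means. Iigp1 had means of 82.5, 27.7 and 15.1 RPKM, and Myl7 lay at 52.5 and 646 RPKM in the control libraries.

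Of 17 clock genes, 3 rose and 8 fell, and 4 rose and 8 fell adjusted over the list alone. Arntl rose by 2.36 (limma adjusted p = 0.00991), and did not pass without a filter on low values (adjusted p = 0.0694). Dbp and Per3 both fell by 1.72, and lost their calls without control replicate 1 (limma adjusted p = 0.0763 and 0.074). The clock list lay at -0.25 relative to all genes (camera adjusted p = 0.00644; adjusted p = 0.358 with an estimated correlation). Of 16 immediate early genes, 2 rose, and 8 adjusted over the list alone. Atf3 rose by 2.19 (limma adjusted p = 0.00264), and the list lay 0.70 above all genes (camera adjusted p = 1.13e-05; adjusted p = 0.426 with an estimated correlation). Cyr61 and Egr1 passed higher without 28 day replicate 2 (limma adjusted p = 0.0134 and 0.0312). Mtrnr2l fell by 2.16 and lost its call without control replicate 1 (limma adjusted p = 0.0828) or control replicate 2 (0.0785).

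At 28 days 318 genes were higher and 171 lower than in the controls by limma (adjusted p under 0.05), of which 98 and 76 changed over 2-fold. The counts were 23 and 10 without control replicate 1, 53 and 39 without control replicate 2, 165 and 66 without 7 day replicate 1, and 174 and 69 without 7 day replicate 2. Without 28 day replicate 1 the lower genes numbered 113. Of 58 named genes that passed, 12 kept their call without any single library: Nppb, Tnfrsf12a, Syt12, Ccl8, Ankrd23, Arntl, Acta1, Cilp, Thbs4, Atf3, Hspb1 and Hspb7. Without a filter on low values 42 of the 58 did not pass, Arntl among them, and 21 did not with only the 2 groups compared. The lists not called at 28 days also held the calcium, endothelial, smooth muscle, chemokine, renin-angiotensin, redox, endoplasmic reticulum stress, red blood cell, adipocyte, mesothelial, atrial, skeletal muscle and sex-specific genes (camera adjusted p from 0.0837 to 0.982). The median, mean and camera direction differed in sign for the smooth muscle, chemokine, calcium, renin-angiotensin, endoplasmic reticulum stress, red blood cell and mesothelial lists. The atrial list was called lower without control replicate 1, at -1.25, and higher without control replicate 2, at 2.23. The red blood cell list was called higher without control replicate 1, at 0.57, and lower without control replicate 2, at -0.64. The adipocyte list was called higher without 28 day replicate 2, at 2.50, and without a filter on low values, at 0.66. Fry called 8 lists at 28 days. Of the lists that camera called, it did not call the crosslinking, neutrophil, complement and interferon lists (adjusted p = 0.0809, 0.0526, 0.261 and 0.124). Nor did it call the fatty acid oxidation, immediate early and ribosomal lists (adjusted p = 0.492, 0.0916 and 0.127).

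The third comparison set 28 days against 7 days, which tests the difference between the infusion times itself. Matrix genes were lower at 28 days. Postn fell by 2.50, from 148 ± 0.361 to 25.7 ± 1.18 RPKM (n = 2; SE 0.10; limma adjusted p = 0.00023). Cthrc1, Col3a1 and Col1a2 fell by 2.98, 2.24 and 1.91. Spp1, Timp1 and Col1a1 fell by 2.70, 2.21 and 1.82, but lost their calls without 7 day replicate 2 (limma adjusted p = 0.0526, 0.0526 and 0.0735). Of 38 genes of collagens and matrix structure, 28 fell and 10 did not pass, and 36 fell when adjusted over the list alone. The median of all genes was -0.12 in this comparison, and the collagen list lay at -1.12 relative to it (camera adjusted p = 1.93e-28; adjusted p = 0.159 with an estimated correlation). Of 30 genes of crosslinking and turnover, 1 rose and 13 fell, and 2 rose and 18 fell adjusted over the list alone. Lox fell by 1.67, and lost its call without 7 day replicate 1 or 2 (limma adjusted p = 0.0592 and 0.122). That list lay at -0.40 relative to all genes (camera adjusted p = 9.83e-06; adjusted p = 0.348 with an estimated correlation). Of 15 fibroblast markers, 9 fell, and 10 adjusted over the list alone, with the list at -0.56 relative to all genes (camera adjusted p = 2.51e-07; adjusted p = 0.159 with an estimated correlation). The TGF-beta list, with 3 lower of 21 and 4 adjusted over the list alone, was not called (camera adjusted p = 0.0672). It was called lower after either rescaling (camera adjusted p = 0.0136 and 0.0168), with the replicate block (0.0304) and without 7 day replicate 1 (0.0377). No filter (camera adjusted p = 0.031), a mean RPKM of at least 5 (0.0231) and fry (0.0487) called it lower too.

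As lists, macrophage, chemokine, interferon and cell cycle genes were also lower at 28 than at 7 days. Of 25 monocyte and macrophage markers, 18 fell, and 22 adjusted over the list alone. Fcgr1, a receptor for IgG, and Ctss, which encodes cathepsin S, fell by 1.94 and 1.62 (limma adjusted p = 0.00264 and 0.00669). That list lay at -0.97 relative to all genes (camera adjusted p = 2.61e-16; adjusted p = 0.177 with an estimated correlation). Of 20 chemokine, cytokine and adhesion genes, 6 fell, and 12 adjusted over the list alone. Ccl8 fell by 1.99, and the list lay at -0.67 relative to all genes (camera adjusted p = 0.000264; adjusted p = 0.342 with an estimated correlation). Of 13 complement and acute phase genes, 4 fell, and 7 adjusted over the list alone, with Serpina3n at -2.06. That list lay at -0.49 relative to all genes (camera adjusted p = 0.00141; adjusted p = 0.403 with an estimated correlation). It was not called without 7 day replicate 2 (camera adjusted p = 0.0799) or 28 day replicate 2 (0.165). Of 23 interferon genes, 12 fell, and all 23 adjusted over the list alone. Isg15, an interferon-induced ubiquitin-like protein, fell by 2.12, and its call was lost without either 7 day library (limma adjusted p = 0.0973 and 0.205) or 28 day replicate 1 (0.115), and after either rescaling (0.0517 and 0.0621). The interferon list lay at -1.36 relative to all genes (camera adjusted p = 1.16e-11; adjusted p = 0.394 with an estimated correlation). Of 17 cell cycle genes, 14 fell, and 15 adjusted over the list alone. Birc5 and Top2a, a DNA topoisomerase, fell by 2.30 and 2.16, and lost their calls without 7 day replicate 2 (limma adjusted p = 0.0526 and 0.0735). The cell cycle list lay at -1.29 relative to all genes (camera adjusted p = 1.94e-12; adjusted p = 0.159 with an estimated correlation). Of 22 redox genes, Hmox1 and Cybb fell, by 1.16 and 1.08, and 10 adjusted over the list alone. The redox list lay at -0.28 relative to all genes (camera adjusted p = 0.0337; adjusted p = 0.339 with an estimated correlation). Both genes lost their calls without either 7 day library (limma adjusted p from 0.0757 for Cybb to 0.248 for Hmox1) and after either rescaling (from 0.063 for Cybb to 0.12 for Hmox1). Hmox1 also lost its call without either control (limma adjusted p = 0.0844 and 0.0858) or 28 day replicate 2 (0.0528), and Cybb without 28 day replicate 1 (0.11). The redox list was not called without 7 day replicate 2 (camera adjusted p = 0.125), without 28 day replicate 2 (0.129) or with a mean RPKM of at least 5 (0.0925). Sod3 passed lower without 28 day replicate 2 (limma adjusted p = 0.0198).

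Fewer genes were higher at 28 than at 7 days. Tcap, the titin cap protein of the Z disc, rose by 1.29, from 665 ± 31.8 to 1622 ± 14.8 RPKM (n = 2; limma adjusted p = 0.00264). Dbp rose by 2.51 and Per2 by 1.91. Of 17 clock genes, 6 rose, and 8 rose and 2 fell adjusted over the list alone. The clock list lay 0.62 above all genes (camera adjusted p = 1.75e-09; adjusted p = 0.159 with an estimated correlation). S100a8 rose by 3.06 (limma adjusted p = 0.0411). Its call was lost without either control (0.0567 and 0.0576), either 7 day library (0.169 and 0.122) or 28 day replicate 2 (0.0699). It was the 1 neutrophil marker of 3 that rose, against 3 adjusted over the list alone, and that list lay 2.59 above all genes (camera adjusted p = 3.69e-05; adjusted p = 0.277 with an estimated correlation). Its median was 2.47, and 0.46 without a filter on low values. Retnlg passed without 28 day replicate 1 (limma adjusted p = 0.0298). Of 19 adult sarcomere genes, 2 rose, also adjusted over the list alone, with the list 0.34 above all genes (camera adjusted p = 9.93e-11; adjusted p = 0.159 with an estimated correlation). Of 13 heat shock genes, 1 rose, and 2 adjusted over the list alone. It was Hspb1, at 0.54, whose call was lost without any of the libraries but 28 day replicate 2 (limma adjusted p from 0.0785 to 0.103). That list lay 0.23 above all genes (camera adjusted p = 6.37e-05; adjusted p = 0.348 with an estimated correlation). Of 77 ribosomal genes 0 passed in limma, over all genes or adjusted over the list alone, and 3 were higher and 3 lower at an unadjusted p under 0.05. The list lay 0.19 above all genes (camera adjusted p = 6.82e-08; adjusted p = 0.403 with an estimated correlation).

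Lists of energy metabolism moved little from 7 to 28 days in their own medians. Of 65 genes of oxidative phosphorylation 0 passed in limma, over all genes or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. The list lay 0.23 above all genes (camera adjusted p = 2.3e-12; adjusted p = 0.403 with an estimated correlation). Of 20 genes of the tricarboxylic acid cycle, 1 rose, also adjusted over the list alone. It was Idh2, an isocitrate dehydrogenase, at 0.71, whose call was lost without either control (limma adjusted p = 0.0824 and 0.0826), either 7 day library (0.0637 and 0.145) or 28 day replicate 2 (0.0694). That list lay 0.21 above all genes (camera adjusted p = 6.74e-05; adjusted p = 0.403 with an estimated correlation). Of 29 genes of fatty acid oxidation, 1 fell, also adjusted over the list alone, which was Ucp3. The list lay 0.15 above all genes (camera adjusted p = 0.000514; adjusted p = 0.417 with an estimated correlation), and was not called without 7 day replicate 2 (camera adjusted p = 0.0895) or 28 day replicate 1 (0.701). Pdk4 passed lower without 28 day replicate 1 (limma adjusted p = 0.00866). Ucp3 fell by 1.24, and lost its call without either control (limma adjusted p = 0.0667 and 0.0678), either 7 day library (0.161 and 0.122) or 28 day replicate 2 (0.0565). After quantile normalization the fatty acid and tricarboxylic acid cycle lists were not called (camera adjusted p = 0.245 and 0.206).

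Among cardiomyocyte genes, Nppb had a log2 change of 0.81 between the times (limma adjusted p = 0.159), Acta1 of -0.33 (0.251), Nppa of 0.16 (0.933) and Atp2a2 of -0.15 (0.487). Ctgf, the growth factor of connective tissue, had 0.68 (limma adjusted p = 0.579). None of these passed. Myh7 had 1.25 (limma adjusted p = 0.0616) and passed without 28 day replicate 1 (adjusted p = 0.0115). Myh6 had 0.19, and was below 0 after quantile normalization. Of 13 hypertrophic and fetal genes, Nes and Uchl1 fell, by 0.94 and 0.84, and 2 rose and 2 fell adjusted over the list alone. Nes lost its call without every library but 28 day replicate 2 (limma adjusted p up to 0.246), and Uchl1 without either 7 day library or 28 day replicate 1 (adjusted p up to 0.188). The hypertrophic list lay 0.38 above all genes (camera adjusted p = 0.00561; adjusted p = 0.342 with an estimated correlation). It was not called without 28 day replicate 1 (camera adjusted p = 0.549) or after either rescaling (0.0831 and 0.486). Of 5 atrial markers, 6 adipocyte markers and 16 immediate early genes 0 passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 immediate early genes were higher and 0 of the other 2 lists. Their lists were called higher with camera adjusted p = 0.00277, 0.0479 and 0.0101, and each had adjusted p = 0.403 with an estimated correlation. The lists lay 2.03, 0.39 and 0.23 above all genes. Without either control, Myl4 passed at 1.90 and Myl7 at 2.24, though no control enters this comparison and neither log2 change moved. Without 28 day replicate 2, Car3, Adipoq and Retn passed higher (limma adjusted p = 0.0121, 0.0211 and 0.0196). None of these 3 lists was called after median ratio scaling (camera adjusted p = 0.0535, 0.144 and 0.0751) or quantile normalization (0.101, 0.258 and 0.101). The immediate early list was not called without 7 day replicate 2 (camera adjusted p = 0.635), without 28 day replicate 1 (0.489) or without a filter on low values (0.0742). The adipocyte list was not called without either 7 day library (0.0752 and 0.108), with a pseudocount of 0.1 (0.0672) or a mean RPKM of at least 5 (0.152), and without 28 day replicate 1 its median was -0.54. Adipocyte genes were high in 28 day replicate 1, with Cfd at 40.0 against 2.34 RPKM in 28 day replicate 2.

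At 28 against 7 days 45 genes were higher and 473 lower by limma (adjusted p under 0.05), of which 15 and 204 changed over 2-fold. The higher genes were 8.69% of the calls as deposited, 21.9% after median ratio scaling and 20.8% after quantile normalization. The counts were 6 and 21 without 7 day replicate 2, 17 and 113 without 7 day replicate 1, 34 and 223 without 28 day replicate 1, and 94 and 595 without 28 day replicate 2. They were 23 and 268 without control replicate 1 and 23 and 263 without control replicate 2. Of 54 named genes that passed, 12 kept their call without any single library. These were Dbp, Per2, Tcap, Cthrc1, Postn, Col3a1, Col1a2, Fcgr1, Ctss, Ccl8, Serpina3n and Hbb-b2. Without a filter on low values 22 of the 54 did not pass, and after either rescaling 11 did not. Hbb-b2 was near 0 outside the 7 day group and shares sequence with other globin genes, so its value is uncertain. The calcium, endothelial, smooth muscle, glycolysis, renin-angiotensin, endoplasmic reticulum stress, red blood cell, mesothelial, skeletal muscle and sex-specific lists were not called (camera adjusted p from 0.0506 to 0.616). The calcium, glycolysis, renin-angiotensin and mesothelial lists differed in sign between median, mean and camera. Without either control the red blood cell list was called lower, at -0.90, as it was after either rescaling and with the replicate block. Without 7 day replicate 1 the endothelial and endoplasmic reticulum stress lists were called lower, at -0.33 both, and the calcium and skeletal muscle lists higher, at 0.01 and 0.52. Without 28 day replicate 2 the endothelial, endoplasmic reticulum stress and smooth muscle lists were called lower, at -0.40, -0.43 and -0.38. That fit also called the renin-angiotensin list higher, at 0.23, and the calcium list, at -0.03, by camera adjusted p = 0.0229. The endoplasmic reticulum stress list was also called after quantile normalization and with the replicate block (camera adjusted p = 0.0175 and 0.0462). Without a filter it was called too (0.0352), as was the renin-angiotensin list, higher (0.033). Fry called 10 lists at 28 against 7 days. Those that camera called and fry did not were the hypertrophic (adjusted p = 0.584), neutrophil (0.14), complement (0.164), interferon (0.124), heat shock (0.306) and ribosomal (0.66) lists. Others of this kind were the fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle, immediate early, adipocyte and atrial lists (adjusted p from 0.483 to 0.786).

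The log2 changes at 7 and 28 days were correlated across the 11096 genes, with Pearson r = 0.58. Genes are not independent replicates, and the comparisons share their controls. In 100 simulations of unchanged groups against shared controls, r was 0.504 on average and 0.652 at the highest. The covariance was 0.107, against a simulated 0.0218 on average and 0.0358 at the highest, a difference from the average of 0.0855. Genes called higher at both times numbered 262, against 41.9 for independent lists, and genes lower at both 91, against 3.88. Another 4 genes were higher at 1 time and lower at the other. The controls are too few to give each comparison its own 2 libraries, so part of the excess may come from the shared controls. Of the genes called higher at 7 days, 356 were lower at 28 than at 7 days, and 317 of these were not called at 28 days. Of the genes called lower at 7 days, 20 were higher at 28 than at 7 days.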

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

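In this part the tests of macrophages and of control level were chosen only after the interferon result was seen, and that of a single library before. Some genes had estimates of opposite sign at 7 and 28 days, and some lists opposite camera directions, with a tested difference between the times that passed, and at least 1 of the 2 effects passing. Their log2 changes from 7 to 28 days are given here. Macrophage and chemokine genes with a fall were Fcgr1 at -1.94, Ctss at -1.62, Cx3cr1 at -1.55, Emr1 at -1.49, Ccl7 at -1.92, Cxcl10 at -1.89 and Ccl12 at -1.50. Fcgr1, a receptor for IgG, passed higher at 7 days and lower at 28 days, with changes of 1.03 and -0.91. The other macrophage and chemokine genes did not pass against the controls at 28 days (limma adjusted p from 0.0663 for Ccl7 to 0.902 for Cx3cr1). Cell cycle genes with a fall were Ccnb2 at -2.28, Ccna2 at -2.22 and Top2a at -2.16, which lay near the controls at 28 days. The interferon genes Rtp4 and Ifi44 changed by -1.90 and -2.147. Tcap, Gnb3 and Gnmt rose by 1.29, 1.40 and 1.26. Tcap fell by 1.11 at 7 days and lay at 0.18 at 28 days. The lists were the adult sarcomere genes at 0.21, the macrophage markers at -1.09 and the cell cycle genes at -1.41 (adjusted p = 0.159, 0.177 and 0.159 with an estimated correlation). The sarcomere median and mean lay above 0 at both times, and only the camera direction differed. The calls of these 3 lists were kept without any single library. Of the genes, Tcap, Fcgr1 and Ctss kept the call of the difference without any single library. The other genes lost it without at least 1, except Rtp4, for which this was not run.

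The interferon list was lower at 28 days than in the controls and lower than at 7 days (adjusted p = 0.426 and 0.394 with an estimated correlation). Fewer macrophages may lower interferon genes, but against the controls the median of macrophage markers was -0.14, and -0.31 without 28 day replicate 1, which argues against it as the main source there. A single library may decide the list, but over the 6 fits each without 1 library the least negative median was -1.06 and the most negative -1.80. A raised level in the controls may make the 28 day values look low. The control libraries lay apart on this list, at 0.39 and -0.39 around their mean, and Iigp1 lay below the controls at 7 days already. As a whole, however, the list also lay at -1.48 against the 7 day libraries, where macrophage markers fell too, with a median of -1.09. The interferon median minus the macrophage median at 28 days against control was -1.25, and ranged from -1.77 to -0.81 without single libraries. As the test was written, this counted against macrophages as the whole source of that fall. It reuses the medians against the controls, however, so it is not separate evidence on the fall from 7 days. In that comparison the 2 medians lay closer together, so fewer macrophages stay open as a source there. An effect of the infusion and a difference in housing or infection between groups of mice were not tested.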

How the results depend on the processing

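Counts below are higher and lower genes by limma. Without a filter on low values they were 45 and 16 at 28 days and 25 and 239 at 28 against 7 days, and the test then covered more genes at a low level. With a mean RPKM of at least 5, which tests fewer genes, 167 were lower at 7 days, and 29 and 266 at 28 against 7 days. Median ratio scaling gave 729 and 426 at 7 days and 225 lower at 28 against 7 days, and quantile normalization 701, 527 and 210. With only the 2 groups compared, which leaves fewer samples, counts were 165 and 69 at 28 days and 23 and 264 at 28 against 7 days. List results were not planned or run for that setting. An unadjusted p under 0.05 was also combined with a fold threshold. That threshold was 2 at 7 days and at 28 against 7 days, but only 1.5 at 28 days. It gave 386 and 59 at 7 days, 483 and 325 at 28 days and 28 and 249 at 28 against 7 days. As the thresholds differ, these counts cannot be compared between 7 and 28 days.

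A replicate block gave 110 lower genes at 28 days. It ended 2 of 59 calls of named genes at 7 days, 7 of 58 at 28 days and 10 of 54 at 28 against 7 days. By limma these included Ndufs1 at 7 days (adjusted p = 0.0553) and Gbp3 and Ifit1 at 28 days (0.0538 and 0.072). At 28 against 7 days they included Isg15, Idh2, Hspb1, Uchl1, Cybb and Hmox1 (limma adjusted p from 0.0515 for Hspb1 to 0.0629 for Hmox1). Col1a1 at 28 days passed with the replicate block (limma adjusted p = 0.0398). Replicates with the same number had correlations of 0.149, -0.0193 and -0.0139 between groups, so the numbers gave no sign of pairing beyond a shared number.

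With an estimated correlation camera called 0 lists at 7 days, 0 at 28 days and 0 at 28 against 7 days. Fry called 13 lists at 7 days, 8 at 28 days and 10 at 28 against 7 days.

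With each library left out in turn, 340 to 1899 genes were higher and 52 to 353 lower at 7 days. At 28 days 23 to 264 were higher and 10 to 147 lower, and at 28 against 7 days 6 to 94 and 21 to 595. Lists called numbered 15 to 17, 13 to 15 and 16 to 25. The correlation of the 7 and 28 day changes ranged from 0.495 to 0.637. Median log2 changes of the red blood cell list at 28 days ranged from -0.64 to 0.57, and those of the atrial list from -3.15 to 0.69 at 7 days and -1.25 to 2.23 at 28 days. The adipocyte list ranged from -0.11 to 2.50 at 28 days and -0.54 to 1.94 at 28 against 7 days, and the interferon list from -0.34 to 0.47 at 7 days. Other lists crossed 0 over narrower ranges. Apart from the smaller gene or sample numbers named, the cause was not tested. A lost call did not always go with a moved estimate. At 28 days the log2 change of Des ranged from 0.85 to 0.95 and that of Actn2 from 0.72 to 0.79. That of Ifit1 ranged more widely, from -2.81 to -1.59.

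Of 244 calls or non-calls of named genes, 222 stayed the same with median ratio scaling, 217 with quantile normalization, 171 without a filter, 223 without a trend and 207 with only the 2 groups compared. With a pseudocount of 0.1 or 1 they were 241 and 239. Leaving out short RNA and date symbols was chosen after the data were seen. It left 11062 genes and all 244 unchanged, with 1496 and 262 genes at 7 days, 350 and 194 at 28 days and 51 and 505 at 28 against 7 days.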

Other observations

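In this part the tests of cardiomyocyte share, of time of day and of Nppa against other atrial markers were chosen only after the results were seen, and that of further atrial genes before. The genes in this and the next paragraph were chosen after their values were seen. Kcnv2, a potassium channel subunit, fell by 1.15 at 7 days (limma adjusted p = 0.00501), without any single library too. Kcnj2, the inward rectifier channel, fell from 10.4 ± 0.542 to 5.26 ± 1.58 RPKM at 7 days (n = 2; limma adjusted p = 0.0177) and by 1.23 at 28 days. Its 7 day call was lost without control replicate 1 (limma adjusted p = 0.12), control replicate 2 (0.079) or 7 day replicate 2 (0.061). Ace, the enzyme that makes Ang II, rose from 10.2 ± 0.786 to 23.2 ± 3.85 RPKM at 7 days, a log2 change of 1.14 (limma adjusted p = 0.00314), and was at 0.23 at 28 days.

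Herpud1, a gene of endoplasmic reticulum stress, fell from 142 ± 3.11 to 51.3 ± 7.02 RPKM at 7 days, a log2 change of -1.47 (limma adjusted p = 0.00265). The chaperones Pdia3, Pdia4 and Manf rose by 0.85, 0.72 and 0.80 at 7 days, and Pdia4 and Manf lost their calls with either rescaling. Kdr, the endothelial receptor for VEGF, rose by 1.04 at 7 days (limma adjusted p = 0.00234), and the tight junction gene Cldn5 by 1.43. Cldn5 lost its call without control replicate 2 (limma adjusted p = 0.053) or either 7 day library (0.052 and 0.07). Sod3, a secreted superoxide dismutase, rose by 1.35 and lost its call without 7 day replicate 2 (limma adjusted p = 0.059).

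Members of lists not called by camera also passed. At 7 days 4 calcium and ion channel genes rose and 3 fell, 4 endothelial genes rose, 2 smooth muscle genes rose and 1 fell, 8 glycolysis genes rose and 1 fell, and 6 redox genes rose. In the same comparison 2 renin-angiotensin genes rose and 2 fell, 4 endoplasmic reticulum stress genes rose and 1 fell, and 6 ribosomal genes rose and 2 fell. Adjusted over the list alone, 12 endoplasmic reticulum stress genes rose and 2 fell, and 0 ribosomal genes passed. The calcium list then had 6 higher and 4 lower, the smooth muscle list 4 and 1, and glycolysis 9 and 1. The red blood cell, adipocyte and mesothelial lists each had 1 higher gene at 7 days. At 28 days 2 calcium genes rose and 3 fell, 1 endothelial gene rose, 4 chemokine genes rose, 1 renin-angiotensin gene and 1 adipocyte gene rose, and 1 endoplasmic reticulum stress gene fell. Adjusted over the list alone, 5 calcium genes rose and 4 fell, 4 chemokine genes rose and 1 fell, and 3 endoplasmic reticulum stress genes fell. At 28 against 7 days 1 renin-angiotensin and 1 red blood cell gene fell, and adjusted over the list alone 5 endothelial genes fell and 1 renin-angiotensin gene rose. Of the lists without enough tested members, the lymphocyte and lung epithelium lists had 0 and the Schwann cell list had 2. Short RNA genes reached large values in single libraries, with Mir208b at 86356.8 RPKM in 7 day replicate 1 alone and Snord55 at 90195.4 RPKM in 7 day replicate 2 alone. Adipocyte genes were higher in 28 day replicate 1 than in replicate 2, with Adipoq at 5.78 against 0.474 RPKM and Retn at 7.34 against 0.202 RPKM.

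Of 2 sets of clock genes chosen after the values were seen, Arntl, Clock, Npas2 and Nfil3 had medians of 1.42 at 7 and 0.90 at 28 days, where Clock did not pass, and Dbp, Tef, Hlf, Per2, Per3, Nr1d2 and Cry2 of -2.13 and -1.28. A lower share of cardiomyocytes might lower the second set, but the sarcomere median of 0.0216 at 7 days argues against it. The 2 sets lay 3.55 apart at 7 days, but as they were picked by their values this decides nothing on another time of day of collection. The labels do not give the time of day, so it stays open. An effect of the infusion on the clock stays open and was not tested.

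Atrial genes differed between the controls, with log2 ratios of 2.90 for Nppa, 3.61 for Myl7 and 3.84 for Myl4, while ventricular genes had a median of 0.03. A varying share of atrial tissue may explain this, and a median under 0.25 in 7 further atrial genes had been set beforehand to count against it. The median was 0.15, so the test as written counted against it. That bound was judged wrong only after the value was seen, because 3 of the 7 lay under 1 RPKM in control replicate 1 and 3 at 5 RPKM or above, which left 1, so the explanation stays open. For Nppa at 7 days over control replicate 1, with a log2 ratio of 3.22, the other 4 atrial markers had a median of 0.36, from -0.14 for Sln to 1.11 for Dkk3, which argues against atrial share as its whole source. This was not tested for Nppa at 28 days, where Myl7, Myl4 and Sln also lay above control replicate 1.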
